A study of Mus musculus with 7 samples.

How the data were processed

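RNA of nucleus pulposus, the gelatinous core of the intervertebral disc, was measured in 7 mice on Affymetrix mouse whole-transcript arrays, 1 array per animal. Per the labels, 4 animals were wild type (WT) and 3 lacked the lactate exporter MCT4, the product of Slc16a3 (MCT4KO), and tissue from the discs of 1 animal made 1 sample, so each array is a separate animal. The descriptions give an age of 13 months to every WT animal and 14 months to every MCT4KO animal, so that age and genotype cannot be told apart. The labels describe littermates from heterozygous parents after 10 generations of backcrossing, while the strain is named C57BL/6 for WT and C57BL/6N for MCT4KO. The sex of the animals is not given in the sources used here.

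The authors deposited 1 log2 expression value per feature and array. The array signals were processed in Affymetrix Expression Console 1.4.1, per the submitters' processing notes. The background correction, normalization and summarisation are not given in the sources used here. That the deposited values are log2 is read from their range, and their highest values exceed what the log2 of a scanner reading can reach, so the scale of the signals was altered before deposit. Fold changes are therefore on the deposited scale. The deposited values were used as they stand, without further normalization.

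Of 28846 features, 22206 were transcript clusters, and 19572 of these carried 1 gene symbol in the platform annotation, 0 carried several, and 2634 carried none here. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, used only for names, chromosome and neighbourhood because the build behind the array annotation is not given in the sources used here. Where a gene had several features, as 55 genes did, the feature with the highest mean was used, and for 12 of these genes the features differed in sign of change. This left 19505 genes. The 5222 negative control features of the array gave the background, with a median of 5.99 and array medians of 5.91 to 6.08. A group was called at background for a gene when each of its arrays read at or below that array's control median, and a fold against such a group was computed against the control medians and given as a lower bound. After the data were seen, list medians were also computed with every value below its array's control median raised to it, without a test. Arrays give no read depth, and the number of animals limits the precision: the median standard error of a log2 change was 0.167.

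All 19505 genes were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, MCT4KO against WT over all 7 arrays, with no covariate and with 5 residual and 4.66 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, and a gene was called changed at an adjusted p under 0.05. Slc16a3 also had an exact two-sided permutation test over the 35 splits of 7 animals into 4 and 3. Gene lists were tested with camera in limma with a preset correlation of 0.01 between genes, adjusted over the 40 lists with at least 5 measured members, out of 42 fixed. Camera with an estimated correlation and fry were run as alternatives, fry both for 1 direction and for either (its mixed test). Within a list, p-values were also adjusted over the list alone. The share of changed genes on chromosome 11, which carries Slc16a3, was tested with Fisher's exact test, two-sided.

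The fit was tested on simulated arrays of 19505 genes with 200 changed genes in each of 20 runs, for the comparison of MCT4KO against WT. It recovered 5.66% of genes changed by 0.5 on the log2 scale, 79.7% of those changed by 1 and 99.6% of those changed by 2, and 5.34% of its calls were unchanged genes. A list shifted by 0.5 was called in 100% of runs and 0.256% of untouched lists were called, in simulated genes that vary independently.

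The lists covered cell types that disc dissection could bring along (muscle, erythroid, neutrophil and myeloid marrow, macrophage, B and T cell, osteoblast and osteocyte, osteoclast, adipocyte, endothelial, annulus fibrosus and tendon, neural and glial, epidermal, end plate and hyaline cartilage), lactate and energy metabolism, acid handling, disc markers and matrix, signalling, stress and other responses, and the neighbours of Slc16a3. They were fixed, like the tests, the main alternatives and the rule for naming genes, before the data were examined. The rule named Slc16a3, then the 12 largest increases and 12 largest decreases among changed genes whose groups did not overlap, leaving out predicted genes, Rik clones, receptor and immunoglobulin segment families and small RNAs. It also named in each list up to 4 members with the smallest p and every changed member, and always Slc16a1, Slc16a7 and Bsg. Members absent from the annotation used here were not analysed here.

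Alternatives were quantile normalization, median centring, leaving out genes below the median, averaging a gene's features, testing every feature, a trended robust variance, array weights, an unmoderated linear model, other thresholds, the animal number as a replicate block, and leaving out each animal in turn. After the data were seen, 4 more were added: leaving out WT 1 and WT 2, leaving out WT 1 and MCT4KO 3, the mean of the Y-linked genes as a covariate, and fitting unnamed features too. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.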

Results

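Nucleus pulposus transcriptomes of 4 WT and 3 MCT4KO mice were compared to ask how loss of the lactate exporter MCT4 alters gene expression in the disc. Each array gave 19505 named genes, and array medians over these genes ran from 6.46 to 6.51 on the deposited log2 scale. No pair of arrays was identical. Pearson's r across genes ranged from 0.990 to 0.995 within WT, from 0.989 to 0.992 within MCT4KO and from 0.983 to 0.992 between the groups. Genes are not independent replicates. The first principal component held 32.2% of the variance and had every WT animal on one side of 0 and every MCT4KO animal on the other. The second component held 19.1%.

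Slc16a3, which encodes MCT4, was lost in every knockout animal. Its log2 value was 13.55, 13.35, 13.61 and 13.40 in WT 1 to 4, and 5.02, 4.98 and 4.47 in MCT4KO 1 to 3. The mean fell from 13.48 ± 0.124 (SD, n = 4) to 4.82 ± 0.306 (SD, n = 3), a log2 change of -8.65 ± 0.165 (SE; limma adjusted p = 6.7e-09; exact permutation p = 0.0286, the smallest that 35 splits allow). All 3 MCT4KO values lay below the control median of their array, at the 18.5th to 29.99th percentile of negative controls, so the loss was at least 179.9-fold. The related transporters did not pass the test. Slc16a1, which encodes MCT1, changed by 0.18 ± 0.247 (adjusted p = 0.80), Slc16a7, which encodes MCT2, by -0.25 ± 0.224 (adjusted p = 0.67) from a level below the control median in both groups, and Bsg, the chaperone of MCT1 and MCT4, by -0.03 ± 0.147 (adjusted p = 0.94).

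Decreases outnumbered increases among called genes, Slc16a3 included: 115 of 19505 genes changed, 92 lower and 23 higher in MCT4KO, and 87 of them by at least 2-fold (69 lower, 18 higher). Over all genes, called or not, 10331 were higher and 9174 lower, with a median log2 change of 0.017. The smallest change called was 0.73 on the log2 scale and the median size was 1.29. Under quantile normalization the split was 53 lower and 24 higher. At an unadjusted p under 0.05 there were 2470 genes, 1346 lower and 1124 higher, where chance gives 975.25. All 115 changed genes had groups that did not overlap, as did 12.0% of all genes, against 5.71% from chance with groups of 4 and 3. The count is sensitive to single animals: it was 61, 40, 18 and 25 without WT 1, 2, 3 and 4, and 35, 64 and 15 without MCT4KO 1, 2 and 3, although all 115 genes kept their sign each time. The 8 genes called in all 7 of these fits were Slc16a3, Prrx1, Mlana, Entpd4, Fam135b, Osbp2, Celf2 and Bcam, of which the last 4 were named after their values were seen. Entpd4 is among genes known to differ between C57BL/6 substrains, and the named strain differs between the groups.

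**Figure D1:**
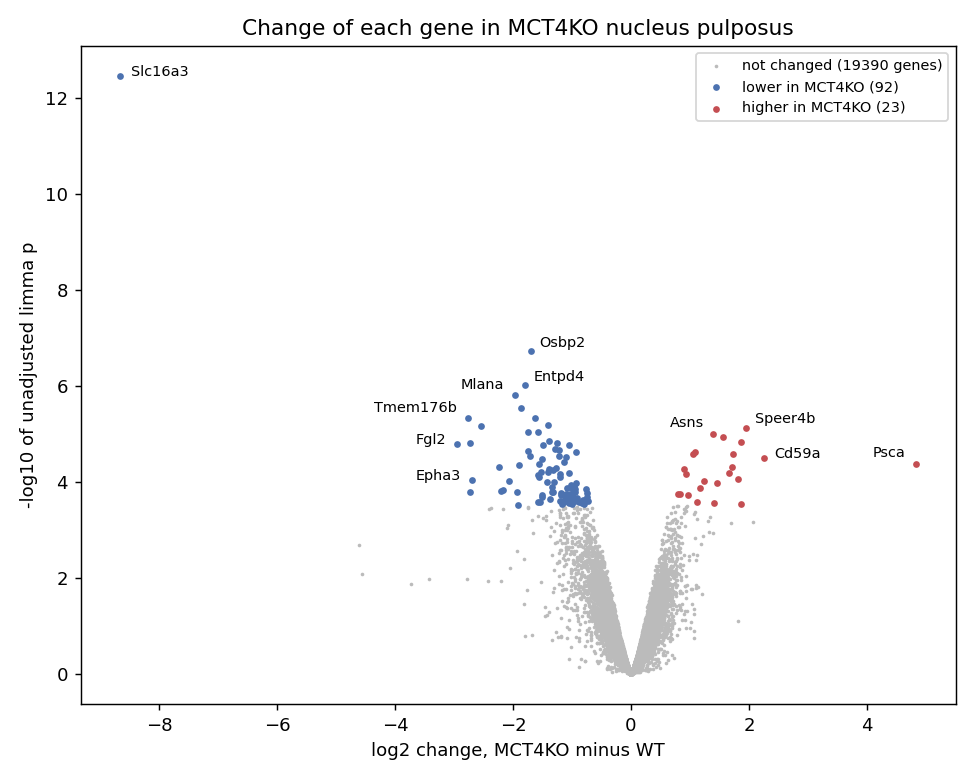
Each point is 1 of 19505 genes, with the log2 change of MCT4KO minus WT on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 92 genes called lower are blue, the 23 called higher are red, and Slc16a3 stands apart at -8.65.

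The largest decrease after Slc16a3 was in Fgl2, a secreted fibrinogen-like protein with immune-regulatory roles, which fell from 13.80 ± 0.797 to 10.85 ± 0.296 (log2 mean ± SD, n = 4 and 3), a change of -2.95 ± 0.372 (SE; adjusted p = 0.016). Tmem176b, a membrane channel protein, fell by 2.77 ± 0.303 (adjusted p = 0.013), and Gabrb2, a GABA-A receptor subunit, by 2.73 ± 0.344 (adjusted p = 0.016). Prrx1, a homeobox factor of limb and skeletal mesenchyme, fell by 2.54 ± 0.290 (adjusted p = 0.014), and Mlana, a melanosomal protein, fell with a change of -1.97 ± 0.190 (adjusted p = 0.0073). Epha3, an ephrin receptor, fell by 2.70 ± 0.421, Sema3d, a secreted semaphorin, by 2.16 ± 0.358, and Plxna2, a semaphorin co-receptor, by 2.07 ± 0.325, with adjusted p of 0.033, 0.040 and 0.033. The other large decreases were in Lrmda (-2.72), Lzts3 (-2.23), Serpina1b (-2.21) and Dmrta1 (-1.93), with adjusted p from 0.024 to 0.041. The MCT4KO animals differed in several of these: Lrmda read 6.01, 6.46 and 8.38, and Epha3 7.67, 7.33 and 5.57, in MCT4KO 1, 2 and 3.

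The largest increase was in Psca, a GPI-anchored surface protein of epithelia, at background in WT (4.73 ± 0.274, n = 4) and at 7.47, 10.00 and 11.21 in MCT4KO 1, 2 and 3. Its log2 change was 4.83 ± 0.684 (SE; adjusted p = 0.023), at least 11.8-fold, with this limit at 24.5 without MCT4KO 1 and 6.68 without MCT4KO 3. Cd59a, an inhibitor of the complement membrane attack complex, rose by 2.25 ± 0.308 (adjusted p = 0.019), Serpina3n, an acute-phase protease inhibitor, by 1.86 ± 0.337 (adjusted p = 0.049), and Asns, the asparagine synthetase induced by amino acid shortage, by 1.39 ± 0.167 (adjusted p = 0.015). Speer4b, Speer4c, Speer4d and Speer4e, members of a repeated gene family on chromosome 5 whose near-identical copies leave each single value uncertain, rose by 1.95, 1.86, 1.73 and 1.66 (adjusted p from 0.014 to 0.027). The WT means of Speer4b (5.93) and Speer4e (5.91) lay just below the control median of 5.99. Rgs9, a regulator of G-protein signalling, rose by 1.13 ± 0.201 (adjusted p = 0.048) and Cavin4, a caveolar coat protein of muscle, by 1.09 ± 0.144 (adjusted p = 0.018). Fscn1 (mean 4.23 in WT and 5.70 in MCT4KO, adjusted p = 0.034) and Cftr (4.59 and 5.82, adjusted p = 0.033) also passed, but these means lie below the control median of 5.99, so their rank among the increases gives no size of change. Of these 24 largest changes, 14, 11, 6 and 8 stayed past the threshold without WT 1, 2, 3 and 4, and 11, 11 and 5 without MCT4KO 1, 2 and 3.

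**Figure D2:**
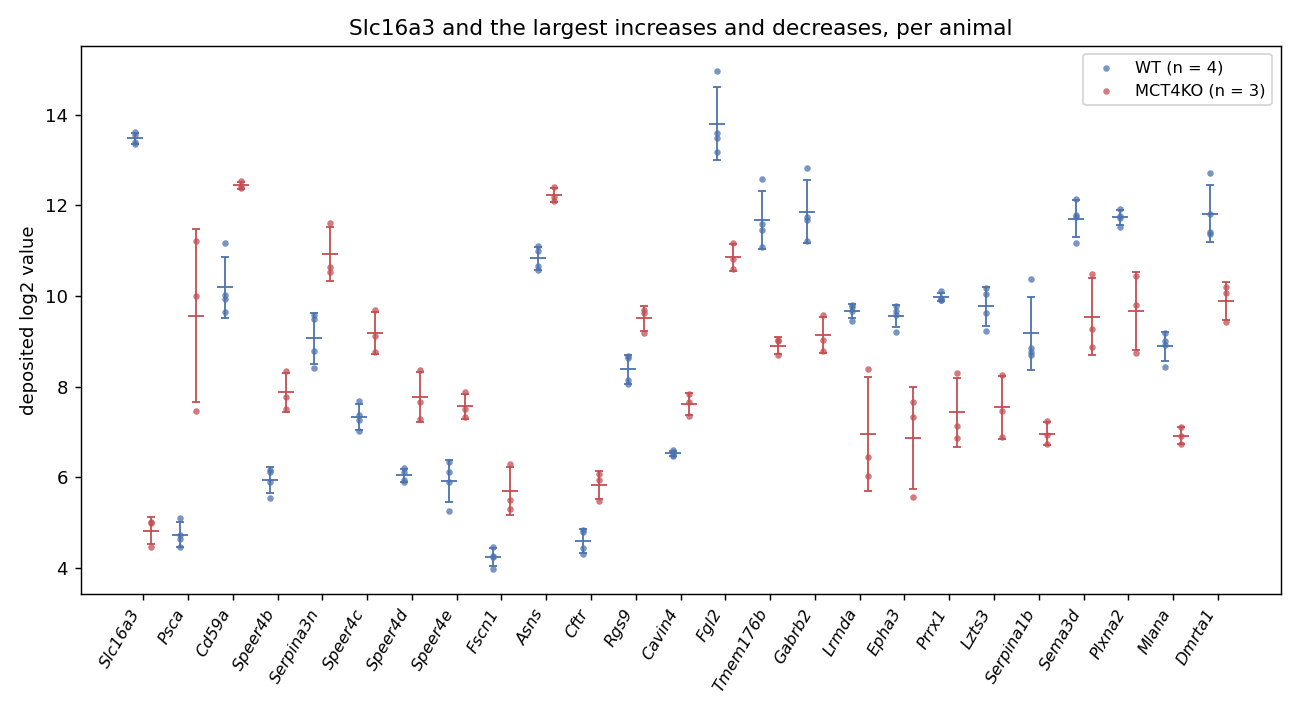
Deposited log2 values of Slc16a3, the 12 largest increases and the 12 largest decreases named by the fixed rule, with a point per animal and bars for mean ± SD of WT (n = 4) and MCT4KO (n = 3). In each gene the points of the groups do not overlap, and Psca shows the widest MCT4KO spread, from 7.47 to 11.21.

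Of 40 gene lists tested, 9 shifted in MCT4KO with camera's preset correlation, 7 lower and 2 higher. None of the 9 passed with an estimated correlation, where 0 lists had an adjusted p under 0.05 and 3 an unadjusted one, and fry called 1 list, cell proliferation, with 5 at an unadjusted p under 0.05. Its test of change in either direction called 10. These included lists that camera did not call: glycosaminoglycan synthesis (adjusted p = 0.0014), unfolded protein response (0.0034) and C57BL/6 substrain differences (0.00098). TCA cycle and pyruvate entry (0.028), pH regulation and bicarbonate handling (0.033) and endothelial markers (0.049) were others. Calls in fits without some animals or genes use the preset correlation alone. Where an array read below its control median and was raised to it, the medians of 20 tested lists came to -0.0079, the difference of the groups' control medians. They included all cell type lists except erythroid, neutrophil, annulus fibrosus and end plate markers. The nucleus pulposus, disc matrix, matrix enzyme, ossification and lactate transport lists were also among them. Of the 35 splits of the animals into 4 and 3, 14 gave 9 or more shifted lists, the real one included. Splits giving a called list a camera p as small as the real one, itself included, were also counted. There were 10 for HIF-1 targets and for neutrophil markers, and 8 for fatty acid oxidation and for the circadian clock. Oxidative stress had 7, cholesterol and fatty acid synthesis 3, and the interferon, epidermal and proliferation lists 2 each.

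Cell proliferation genes were lower in MCT4KO. Of 38 measured members, 34 were below 0, 3 fell over all genes tested and 18 fell adjusted over the list alone, with a median of -0.54 (camera adjusted p = 1.3e-14; adjusted p = 0.052 with an estimated correlation; fry adjusted p = 0.0088). With 4 members at background in both groups and 6 in MCT4KO alone, the median with values raised to the control medians was -0.29. Mki67, the proliferation antigen Ki-67, fell by 1.75 ± 0.207 (adjusted p = 0.015), Rrm2, a ribonucleotide reductase subunit, by 1.54 ± 0.275 (adjusted p = 0.048) and E2f8, a cell cycle transcription factor, by 0.99 ± 0.1799 (adjusted p = 0.049). The MCT4KO mean of E2f8 (5.82) lay below the control median of 5.99, so its size of change is uncertain. The mean over the list was 7.03 to 7.26 in WT animals and 6.57 to 6.71 in MCT4KO animals. The mean of the neutrophil and marrow markers was 5.56 to 8.61 in the same WT animals and 4.99 to 5.41 in the MCT4KO animals.

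Neutrophil and myeloid marrow markers were lower, with a median of -0.74 and a mean of -1.59 over 15 members (camera adjusted p = 3.5e-05; adjusted p = 0.80 with an estimated correlation). No member fell over all genes tested and 4 fell adjusted over the list alone. Mmp8 and Mmp9 also belong to the matrix enzyme list and Lcn2 to the cytokine list. S100a8 and S100a9 encode the subunits of neutrophil calprotectin, and Ngp a granule protein. S100a8 and Ngp read at background in MCT4KO, at least 13.6-fold and 10.8-fold below WT (adjusted p = 0.12 and 0.22 over all genes), and S100a9 changed by -3.72 ± 1.23 (adjusted p = 0.27). The MCT4KO mean of S100a9 (5.70) lay below the control median of 5.99, so its size of change is uncertain. WT 2 read highest for S100a8 and Ngp, and their limits were 6.38 and 4.19 without WT 2, 21.8 and 20.02 without WT 3, and 21.1 and 18.4 without WT 4. The list means were 6.92, 8.61, 5.56 and 5.84 in WT 1 to 4 and 5.41, 5.02 and 4.99 in MCT4KO 1 to 3, so WT 1 and WT 2 carried most of the difference. Without them the median was -0.24 (adjusted p = 0.022), against -0.33 without WT 2 alone. The median was -3.43 without genes below the median, but that filter uses the mean over all arrays. It keeps members at background in MCT4KO only where WT is high, so that value follows in part from the filter. Of the 15 members, 3 were at background in both groups and 7 in MCT4KO alone, and with values raised to the control medians the median was -0.37. The other blood and immune lists did not pass: erythroid markers had a median of -0.20, with 6 of 6 measured members below 0 (adjusted p = 0.33), macrophage markers -0.07 (adjusted p = 0.38; Lyz2, shared with neutrophils, was at background in MCT4KO, at least 2.98-fold below WT, or 1.73-fold without WT 2 and 4.74-fold without WT 4, adjusted p = 0.24) and B and T cell markers 0.09 (adjusted p = 0.46). Of the macrophage markers 7 of 13, and of the B and T cell markers 6 of 9, were at background in both groups.

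Interferon-stimulated genes were lower, with a median of -0.36 over 34 members (camera adjusted p = 3.5e-05; adjusted p = 0.67 with an estimated correlation). No member fell over all genes tested, where 13 had an unadjusted p under 0.05 in that direction, and 4 fell adjusted over the list alone: Rsad2 (-1.12 ± 0.262), Rtp4 (-0.84 ± 0.204), Ifit1 (-1.05 ± 0.254) and Irgm1 (-1.25 ± 0.343), antiviral effectors and cofactors. Rsad2 and Ifit1 had MCT4KO means of 5.44 and 5.60, below the control median of 5.99, so their sizes of change are uncertain. Of the 34 members, 11 were at background in both groups, and with values raised to the control medians the list median was -0.34. The list median was -0.21 without MCT4KO 1 (adjusted p = 0.0030). Every MCT4KO animal had a lower list mean (6.95 to 7.27) than every WT animal (7.41 to 7.53), as also held for neutrophil markers.

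Lists of lipid metabolism were lower along with neutrophil markers (median -0.74). Fatty acid oxidation genes had a median of -0.26, with 23 of 26 members below 0 (camera adjusted p = 3.5e-05; adjusted p = 0.80 with an estimated correlation). The list means were 9.25 in WT 1 and 8.975 to 8.999 in the other WT animals, and 8.45, 8.82 and 8.93 in MCT4KO 1 to 3. The median was -0.09 without MCT4KO 1 (adjusted p = 0.028) and -0.15 without WT 1 and WT 2 (adjusted p = 0.0054). Cd36, a fatty acid transporter, fell adjusted over the list alone (-1.68 ± 0.337; adjusted p = 0.067 over all genes) and was the 1 member to do so. Cpt1a, which starts mitochondrial import, had -0.93 ± 0.277 (adjusted p = 0.22). Cholesterol and fatty acid synthesis genes had a median of -0.13 over 28 members (camera adjusted p = 0.023; adjusted p = 0.42 with an estimated correlation), with 0 called over all genes and 3 lower adjusted over the list alone, Cyp51 (-0.66 ± 0.165), Acly (-0.63 ± 0.159) and Dhcr7 (-0.97 ± 0.248). This call ended without WT 4 (median -0.13, adjusted p = 0.085), without MCT4KO 3 (-0.08, adjusted p = 0.074) and without WT 1 and MCT4KO 3 (-0.07, adjusted p = 0.097). It also ended with quantile normalization (adjusted p = 0.21), without genes below the median (0.29) and with the replicate block (0.080), at medians of -0.06, -0.13 and -0.13. Glycolysis and glucose uptake genes did not shift, with a median of 0.05, a mean of -0.02 and a test direction of down (adjusted p = 0.88), and 0 of 29 members were called by limma under either adjustment (2 at an unadjusted p under 0.05, Pfkl at -0.81 ± 0.219 and Pdk4 at -0.86 ± 0.294). Lactate and monocarboxylate transport, without Slc16a3 itself, had a median of -0.02 with the test leaning up (adjusted p = 0.98), TCA cycle and pyruvate entry -0.02 (adjusted p = 0.25) and nuclear-encoded oxidative phosphorylation -0.06 (adjusted p = 0.35). The medians of the last 2 turned positive under quantile normalization, at 0.04 and 0.004. In the TCA list Gpt2, an alanine transaminase, fell adjusted over the list alone, to background in MCT4KO and by at least 1.46-fold (adjusted p = 0.098 over all genes). Of the 18 lactate and monocarboxylate transport members, 11 were at background in both groups. Mitochondrially encoded genes were not analysed here.

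HIF-1 target genes were higher as a list, with a median of 0.27 and 31 of 35 members above 0 (camera adjusted p = 0.00020; adjusted p = 0.80 with an estimated correlation). No member rose over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05, among them Higd1a (0.59 ± 0.147), Ero1a (0.63 ± 0.166) and Car9 (0.58 ± 0.157). The list means were 12.41 and 12.39 in WT 1 and WT 2, 12.78 and 12.87 in WT 3 and WT 4, and 12.72 to 13.09 in MCT4KO animals, so the groups overlapped. The call ended without MCT4KO 3 (median 0.12, adjusted p = 0.070), without WT 1 and MCT4KO 3 (median 0.13, adjusted p = 0.33) and without WT 1 and WT 2, the animals with the highest neutrophil markers (median 0.12, adjusted p = 0.44). The list of pH regulation and bicarbonate handling, which shares Car9, had a median of 0.03 (adjusted p = 0.49) and 0 of 34 members called, with 4 higher and 2 lower at an unadjusted p under 0.05.

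Oxidative stress genes were lower, with a median of -0.25 and 27 of 33 members below 0 (camera adjusted p = 0.00095; adjusted p = 0.80 with an estimated correlation, 0.20 without MCT4KO 1 and 0.095 without genes below the median). The median was -0.09 without MCT4KO 1, -0.26 without genes below the median and -0.16 without WT 1 and WT 2 (adjusted p = 0.022). Mt1, a metallothionein, fell by 1.11 ± 0.188 (adjusted p = 0.041), and 3 members fell adjusted over the list alone, Mt1, Mt2 (-2.41 ± 0.450; adjusted p = 0.053 over all genes) and Gpx3, an extracellular glutathione peroxidase (-0.91 ± 0.243). Circadian clock genes had a median of -0.33 over 19 members (camera adjusted p = 0.042; adjusted p = 0.80 with an estimated correlation), with Nr1d1 (-1.58 ± 0.309) and Npas2 (-1.22 ± 0.309) lower adjusted over the list alone. The list mean of WT 1 (10.97) lay below those of the MCT4KO animals (11.03 to 11.29), and the other WT means were 11.51 to 11.66. That call ended without WT 2, 3 or 4 (medians -0.20, -0.30 and -0.17, adjusted p = 0.12, 0.10 and 0.085) and without MCT4KO 1 or 2 (medians -0.33 and -0.24, adjusted p = 0.075 and 0.14). The p was smaller without WT 1 (median -0.36, adjusted p = 0.00026), without WT 1 and WT 2 (-0.38, adjusted p = 0.00058) and without WT 1 and MCT4KO 3 (-0.43, adjusted p = 7.7e-05). It also ended with quantile normalization (0.17), without genes below the median (0.29), with the Y-linked mean as a covariate (0.072) and with the replicate block (0.080), at medians of -0.26, -0.35, -0.33 and -0.17. Epidermal markers were higher as deposited, with a median of 0.28 over 9 members (camera adjusted p = 0.023; adjusted p = 0.42 with an estimated correlation). The call ended without WT 3 (median 0.22, adjusted p = 0.056), without MCT4KO 1 (0.22, adjusted p = 0.075) and with quantile normalization (0.19, adjusted p = 0.13). Krtdap, a keratinocyte differentiation protein, rose adjusted over the list alone (2.07 ± 0.422; adjusted p = 0.071 over all genes). Of the 9 members 5, Krt14 and Krt1 among them, were at background in both groups, and with values raised to the control medians the list median was -0.0079. The median was 0.13 without WT 1 and MCT4KO 3.

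**Figure D3:**
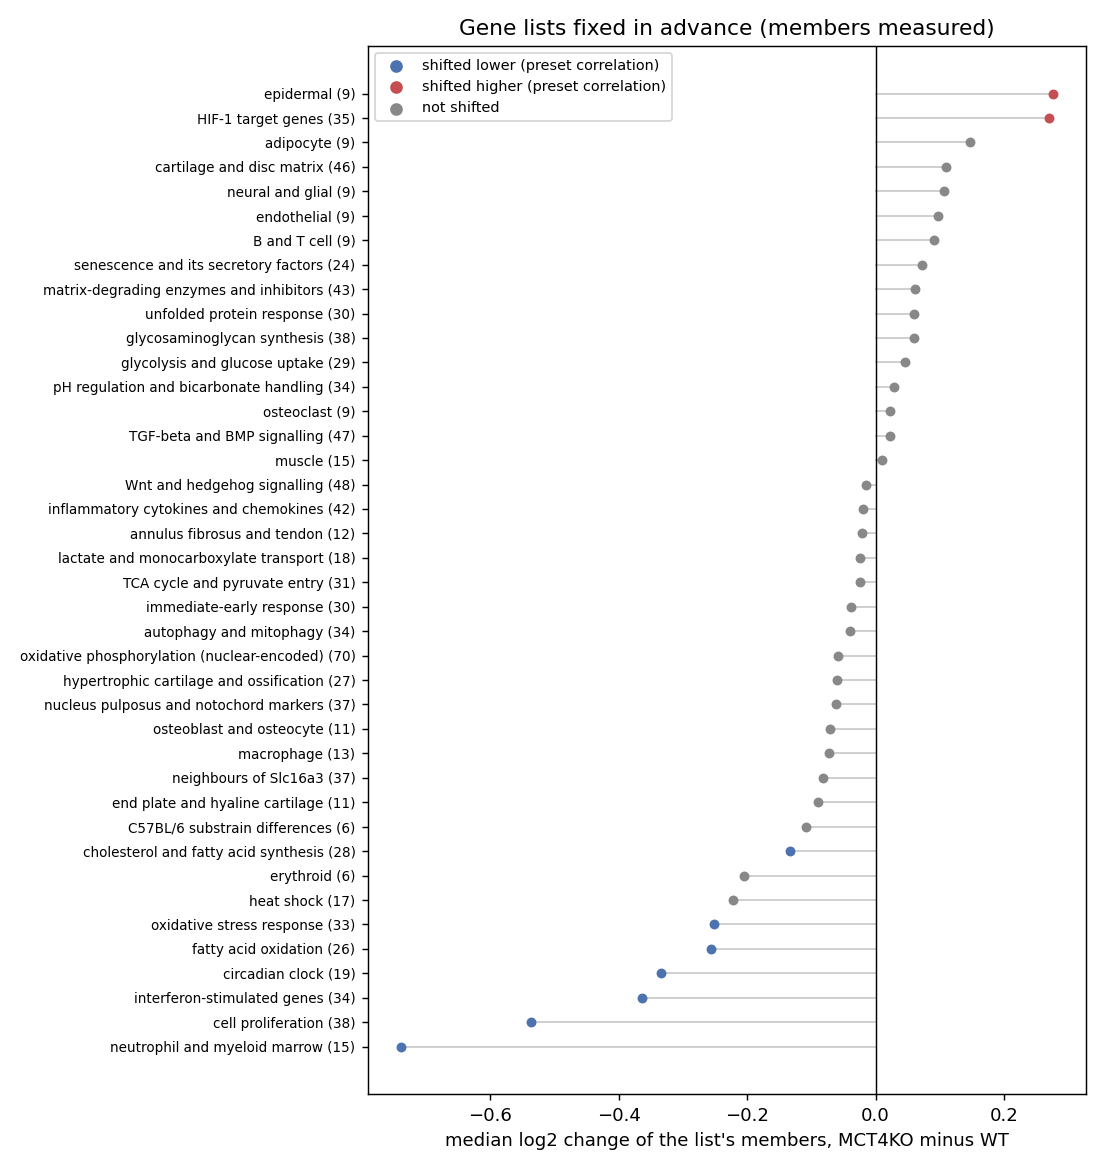
Median log2 change (MCT4KO minus WT) of the measured members of each of 40 gene lists, with the number of members in brackets. Blue and red points are the 7 lower and 2 higher lists called with the preset correlation, and grey points are the 31 others, with neutrophil markers lowest at -0.74 and epidermal markers, of which 5 of 9 were at background in both groups, highest at 0.28.

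**Figure D4:**
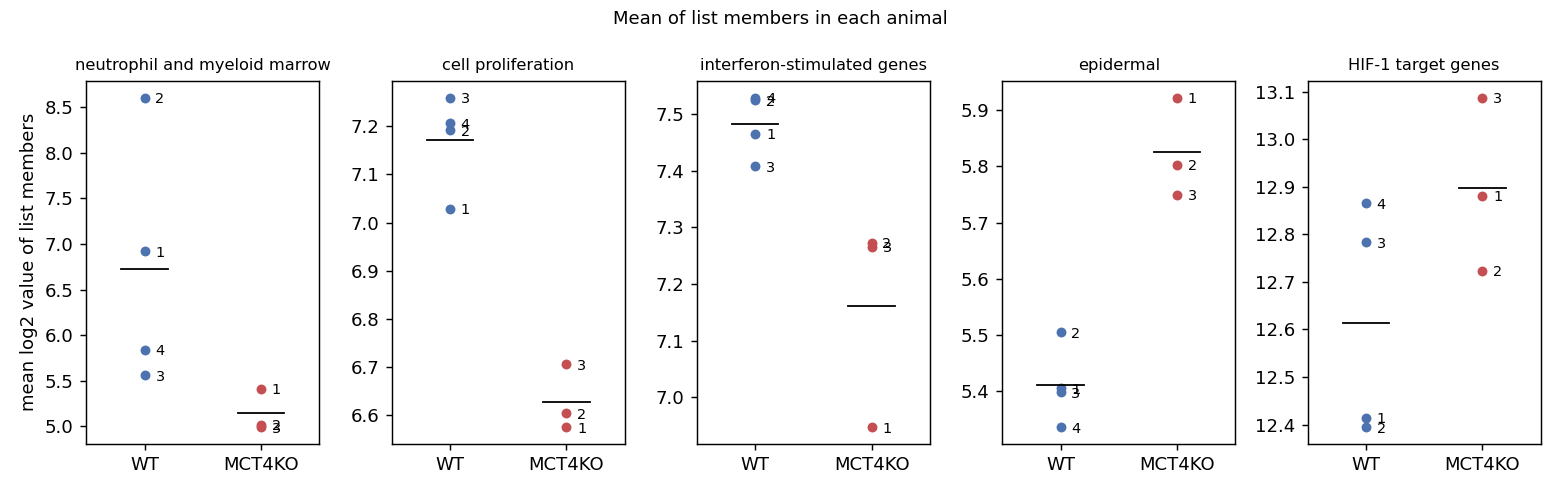
Mean log2 value of the list members in each animal, with the animal number beside each point, a line at the group mean, and a separate vertical scale per list. Cell proliferation runs from 7.03 to 7.26 in WT and from 6.57 to 6.71 in MCT4KO, and neutrophil markers reach 8.61 in WT 2.

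Lists of the disc tissue itself did not pass camera's test. Nucleus pulposus and notochord markers had a median of -0.06 over 37 members (adjusted p = 0.81), with 0 members called by limma, 1 higher and 3 lower at an unadjusted p under 0.05, and Ptn, a heparin-binding growth factor, had the smallest p (-0.55 ± 0.132; adjusted p = 0.12). Cartilage and disc matrix genes had a median of 0.11, a mean of -0.03 and a test direction of up (adjusted p = 0.46), and adjusted p = 0.021 with a median of 0.26 without MCT4KO 3 (0.038 and 0.25 without WT 1 and MCT4KO 3). Snorc, a chondrocyte proteoglycan, fell by 1.53 ± 0.227 (adjusted p = 0.026) and Col2a1, the type II collagen chain, rose adjusted over the list alone (1.32 ± 0.286; adjusted p = 0.088 over all genes), the 2 matrix genes called that way. Glycosaminoglycan synthesis had a median of 0.06 (camera adjusted p = 0.73; adjusted p = 0.0014 in fry's test of either direction). Chpf, a chondroitin polymerizing factor, fell by 1.02 ± 0.178 (adjusted p = 0.045). Matrix-degrading enzymes and inhibitors had a median of 0.06, a mean of -0.02 and a test direction of up (adjusted p = 0.59), with Adamts1 at -1.82 ± 0.483 (adjusted p = 0.16). Hypertrophic cartilage and ossification had a median of -0.06 (adjusted p = 0.46), with Ibsp, bone sialoprotein, at -1.94 ± 0.485 (adjusted p = 0.14) and Col10a1, the collagen of hypertrophic chondrocytes, at 1.81 ± 0.920 (adjusted p = 0.45), where MCT4KO 1, 2 and 3 read 12.11, 9.02 and 7.18.

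The unfolded protein response had a median of 0.06 (camera adjusted p = 0.48; adjusted p = 0.0034 in fry's test of either direction), with Asns its 1 changed member of 30. Inflammatory cytokines and chemokines had a median of -0.02 (adjusted p = 0.46) and Cxcl12 fell adjusted over the list alone (-1.45 ± 0.291; adjusted p = 0.067 over all genes). Senescence factors had a median of 0.07, a mean of -0.09 and a test direction of down (adjusted p = 0.73). TGF-beta and BMP signalling had a median of 0.02 (adjusted p = 0.55), and 0.11 without genes below the median (adjusted p = 0.047). Wnt and hedgehog signalling had a median of -0.01 (adjusted p = 0.67), and autophagy and mitophagy -0.04 (adjusted p = 0.46), with a sign that turned under quantile normalization. Heat shock genes had a median of -0.22 (adjusted p = 0.35) and immediate-early genes -0.04 (adjusted p = 0.48), and without WT 1 these became -0.27 (adjusted p = 0.018) and -0.54 (adjusted p = 1.5e-06). Both also passed without WT 1 and WT 2 (medians -0.34 and -0.44, adjusted p = 0.00018 and 9.1e-05) and without WT 1 and MCT4KO 3 (medians -0.36 and -0.79, adjusted p = 0.00085 and 9.9e-08). Members of these lists moved together, with estimated correlations of 0.54 and 0.69, and the adjusted p with them was 0.82 and 0.89 over all animals.

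The remaining cell type lists did not pass with camera. Medians were 0.01 for muscle (adjusted p = 0.46, and a median of 0.30 with adjusted p = 0.047 without WT 3), -0.07 for osteoblast and osteocyte (0.44), 0.02 for osteoclast with a mean of -0.06 (0.88), 0.15 for adipocyte (0.22, and a median of 0.28 with adjusted p = 0.033 without WT 1 and MCT4KO 3), 0.10 for endothelial (0.46), -0.02 for annulus fibrosus and tendon (0.46) and 0.11 for neural and glial markers (0.46). The muscle and osteoclast medians turned negative under quantile normalization. Members at background in both groups were 7 of 9 endothelial and 7 of 11 osteoblast and osteocyte markers. They were 5 of 9 in each of the osteoclast, adipocyte and neural lists and 6 of 15 muscle markers. These lists therefore say little on whether the groups held equal amounts of such tissue. End plate and hyaline cartilage markers had a median of -0.09 (adjusted p = 0.40) and 1 changed member, Snorc. Their mean was 9.67 in MCT4KO 1 against 8.26 and 7.52 in MCT4KO 2 and 3, and without MCT4KO 1 the median was -1.06 (adjusted p = 0.0016).

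Genes around the targeted locus were examined as a set of their own. Chromosome 11 held 7 of 115 changed genes (6.09%) against 7.56% of all genes (Fisher's exact odds ratio 0.79, 95% interval 0.310 to 1.69, p = 0.72). The 37 neighbours of Slc16a3 had a median of -0.08 (camera adjusted p = 0.33), with 0 called by limma and 4 lower at an unadjusted p under 0.05. Genes known to differ between C57BL/6 substrains can differ in either direction. Over the 6 measured, fry's test of change in either direction gave an adjusted p of 0.00098, its test of 1 direction 0.095 (unadjusted p = 0.0095), and camera 0.33, with a median of -0.11 and 3 members at background in both groups. Besides Entpd4, only Cyfip2 had an unadjusted limma p under 0.05, and it read below the control medians in all 7 animals. The result of the either-direction test therefore need not reflect the list as a whole. Entpd4, an ectonucleotidase of intracellular membranes, was the 1 member of this list called over all genes or adjusted over the list alone. It fell by 1.80 ± 0.164 (adjusted p = 0.0061), and its second feature read -1.55 ± 0.196.

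Y-linked genes differed between animals within groups. The mean of the 3 measured Y-linked genes, Eif2s3y, Kdm5d and Uty, was 3.72 in WT 1 and 4.04 in MCT4KO 3, below the control medians, and 9.69 to 10.06 in the other 5 animals, so that 1 animal of each group lacked their signal. This list was too short for a test. With that mean as a covariate 114 genes changed, 92 of them among the 115.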

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

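The tests of shared probes and of marrow cells, the fit with the Y-linked mean, the fit with unnamed features and the rule for which genes count as the repeated family were chosen only after the results were seen. The number of changed genes was set against all 35 splits of the 7 animals into 4 and 3. Only 1 split, the real one, gave 115 genes, and the highest other split gave 1. That argues against chance assignment of animals for that count. It does not exclude it, because 1 of 35 is the smallest share that these splits allow. The same held for genes changed at least 2-fold, with 1 split at 87 and the highest other at 1. It did not hold for the number of shifted gene lists: 14 of the 35 splits gave 9 or more, and the highest other gave 16, so chance is not argued against there.

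Genes counted here as repeated-family genes, by name and chromosome and without a check of their sequence, were higher in MCT4KO. Of 23 genes higher, 11 were Speer4 genes or predicted or repeated genes on chromosomes 5 (8 genes) and 4 (3 genes), with log2 changes of 0.79 to 1.95, and all 10 measured Speer genes were above 0 (9 of 10 under quantile normalization). One candidate explanation is that near-identical copies share probes and so count as 1 observation. The median pairwise correlation of the members' deviations from their group means was 0.44. That is above the 95th percentile of random gene sets (0.164) but short of the 0.5 set for it, which leaves it open. The median also includes pairs between chromosomes 5 and 4, which may not be copies of each other, so it cannot decide on shared probes. Another is a strain difference that reaches the neighbouring genes: among other genes within 5 Mb the odds ratio of an unadjusted p under 0.05 was 1.67 (95% interval 1.20 to 2.29), an interval that holds the 2 set as the mark of a cause, so the effect of strain cannot be told apart; a version without predicted or repeated-family neighbours, run first and not the one set beforehand, gave 1.27 (0.862 to 1.82). A difference in genotype, age or strain naming between the groups remains open and untested.

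Cell proliferation genes were lower in MCT4KO, with a median log2 change of -0.54, or -0.29 with values below the control medians raised to them. Dividing marrow cells that came with the neutrophil signal could be a source: without WT 1 and WT 2 the median was -0.41 (95% bootstrap interval over members -0.75 to -0.24), which lies below 0 but crosses the bound of -0.3, so this cannot be told apart, although WT 3, with the lowest WT neutrophil mean (5.56), had the highest proliferation mean (7.26) and S100a8, among the most abundant neutrophil transcripts, read 13.04 in WT 2 against 7.71 in WT 3. Unequal sex of the animals is argued against by the Y-linked signal, which was missing in 1 animal of each group. With the Y-linked mean as a covariate the median was -0.54 (interval -0.68 to -0.31). A covariate so evenly spread could hardly move the median, so that fit adds little. A shift of all dim genes is argued against by the list median standing at percentile 0 of 10000 lists matched on mean expression (central 95% from -0.09 to 0.11). Of the 35 splits, 2 gave the list a camera p as small as the real one (real 3.3e-16, the other 2.4e-16), so chance is not excluded at 5%, and the other split differs from the real one in setting WT 1 with the MCT4KO animals. Genotype, the 1-month difference in age and the difference in named strain stay open as biological explanations and were not tested apart.

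Among 225 sets of 4 WT values, 25 (11.1%) had 1 animal far from the other 3 for the range of the set, and MCT4KO, with 3 animals, was not tested. Chance gives about 1 in 20 for independent sets. These sets hold named genes and list means that share members, so the share measures no excess of outlying animals. The ratio given for each is the gap to the nearest animal over the whole range, so small gaps can be flagged, as for Tubb3 (6.46 against 6.56 to 6.57). WT 1 stood low for the Y-linked genes Eif2s3y (3.53 against 11.28 to 11.58, ratio 0.964), Uty (3.26 against 10.39 to 10.87, ratio 0.937) and Kdm5d (4.36 against 7.24 to 7.73, ratio 0.856) and for their mean (ratio 0.945). WT 1 was also low for Nlrp12 (ratio 0.935), Tubb3 (0.891), the unfolded protein response mean (10.97 against 11.32 to 11.33, ratio 0.976) and the senescence mean (8.04 against 8.28 to 8.31, ratio 0.896). It was high for Serpina1b (10.36 against 8.69 to 8.86, ratio 0.902), Acly (ratio 0.918), Rtp4 (0.849), Gpx3 (15.39 against 14.34 to 14.52, ratio 0.831) and the fatty acid oxidation mean (9.25 against 8.975 to 8.999, ratio 0.915). WT 2 was high for Fcer1g (5.60 against 4.62 to 4.77, ratio 0.844), Cyfip2 (0.859) and the mean of pH regulation genes (7.25 against 7.16, ratio 0.971). WT 3 was high for Slc16a7 (ratio 0.916) and the muscle mean (6.15 against 5.60 to 5.64, ratio 0.915), and low for Mt2 (15.43 against 16.94 to 17.23, ratio 0.842), Esam (0.883), Trib3 (0.875), Thbs4 (0.854) and Dkk3 (0.830). Fcer1g, Cyfip2 and Slc16a7 read below the control medians in all 7 animals. WT 4 was high for Chst11 (ratio 0.885) and low for Ndufs6 (0.831).

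Transcript clusters without a gene name here held signal as well: in a fit over all 22206 clusters, 6 unnamed ones passed the adjusted threshold, 2 higher and 4 lower in MCT4KO.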

How the results depend on the processing

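The alternatives of leaving out WT 1 and WT 2, leaving out WT 1 and MCT4KO 3, the Y-linked mean as a covariate and fitting unnamed features were chosen after seeing the data, 4 in all. Slc16a3 passed in every fit, with log2 changes of -8.45 to -8.75 (-8.48 to -8.75 with 1 animal left out). No named gene or list changed direction past the threshold. The count of 115 changed genes (23 higher, 92 lower) stayed within 1.5 times with median centring, quantile normalization (its 53 lower excepted), feature averaging, every feature, the dim-gene filter, a trended robust variance, array weights and the Y-linked covariate. It was 1 (0 higher, 1 lower) without moderation, 16 (2, 14) without WT 1 and WT 2, 17 (1, 16) without WT 1 and MCT4KO 3, 53 (13, 40) with unnamed features, 263 (75, 188) at an adjusted p under 0.1 and 230 (41, 189) at an unadjusted p under 0.05 with 2-fold change. Leaving out 1 animal gave 15 to 64 genes, 1 to 17 higher and 13 to 48 lower, in fits with fewer samples. The cause was not tested. Among named genes, 3322 values kept their side of the threshold, 274 lost and 13 gained a call, and among lists 616, 40 and 12. The kept values include those of genes and lists not called in the main fit. They therefore do not measure how well calls held, and the losses come only from called genes and from the 9 called lists.

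No pairing by animal number was seen across genes: deviations of same-numbered animals correlated at -0.127, 0.016 and 0.050. A pairing that touches few genes would not show in these values. With the number as a replicate block, on 6 animals, 6 genes were called (2 higher, 4 lower), and the calls of the cholesterol and circadian lists ended (adjusted p = 0.080 for both). The 9 shifted lists were 0 with an estimated correlation and 1 with fry, and 6 to 11 otherwise (7 to 11 with 1 animal left out). The chromosome 11 odds ratio was 0.68 without Slc16a3 and 0.95 at an unadjusted p under 0.01. Of the 115 calls, 8 rest on a group at background.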

Other observations

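Several further genes with small p were chosen here after their values were seen. Osbp2, an oxysterol-binding protein, fell by 1.70 on the log2 scale (limma adjusted p = 0.0018), the smallest p after Slc16a3, and Ephx4, an epoxide hydrolase family member, by 1.62 (adjusted p = 0.013). Tmem176a, the neighbour of Tmem176b on chromosome 6, fell by 1.89 (adjusted p = 0.023). Slc12a2, the sodium-potassium-chloride cotransporter NKCC1, fell from 17.25 to 16.06 (adjusted p = 0.041), Foxp1 by 1.497 (adjusted p = 0.016) and Tcf4 by 1.06 (adjusted p = 0.016). Ccnd2, a D-type cyclin, fell by 1.58 (adjusted p = 0.028), Stmn1, a microtubule regulator, by 1.51 (adjusted p = 0.020) and Pbk, a mitotic kinase, by 1.58 (adjusted p = 0.048), all 3 outside the proliferation list. C1galt1, the next protein-coding gene to Asns on chromosome 6, rose by 0.94 (adjusted p = 0.027).

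Changed genes were unevenly spread over chromosomes when all 21 were tested with Fisher's exact test after the data were seen. Chromosome 5 held 18 of the 115, 9 higher and 9 lower (odds ratio 3.03, 95% interval 1.72 to 5.06, Benjamini-Hochberg adjusted p = 0.0025), of which 8 were counted here as repeated-family genes, and chromosome 15 held 11, 1 higher and 10 lower (odds ratio 2.81, interval 1.35 to 5.26, adjusted p = 0.035). Neighbouring genes are not independent, so these p-values are too small.

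WT 1 read low for the immediate-early list, with a mean of 10.05 against 11.99 to 12.54 in WT 2 to 4 and 10.92 to 12.05 in the MCT4KO animals.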
